A study of Mus musculus with 24 samples.

How the data were processed

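The data are raw read counts per Ensembl gene from 24 mouse brain tumours. Each mouse received CT-vIII glioma cells in the right hemisphere. The pumps ran at 0.5 µl/h for 72 h, from day 6 to day 9, and carried D2C7-IT at 0.2 µg, aCD40 at 10 to 300 µg, both, or 2% serum albumin in saline with 100 µg of a rat IgG2a control antibody, per the labels' protocols. The aCD40 dose of each tumour is not given in the sources used here, so the means and SDs of the aCD40 and combination groups may mix doses. The labels put 3 tumours in each of 8 groups (vehicle, aCD40, D2C7-IT and D2C7-IT+aCD40, at day 0 and at day 3 after treatment), and every column was matched to its tumour by name. Total RNA came from flash-frozen tissue, was enriched with oligo(dT) beads and was made into libraries with the NEBNext Ultra RNA kit, which does not mark strand. The tissue was not sorted, so each value mixes tumour, brain, immune and blood cells.

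The authors deposited counts as whole numbers that were not normalized. The submitters' processing notes name bcl2fastq 2.17, Trimmomatic 0.36, STAR 2.5.2b and featureCounts of Subread 1.5.2 with the GRCm38 build. The annotation release and the strand setting are not given in the sources used here. The 6 deposited tables hold 36 columns of 49315 genes, of which 12 repeat another column, with 0 that differ from it. Gene symbols and positions (GRCm38, start and end of the gene) came from GENCODE M21, which names 49056 of the identifiers. Because strand was not marked, reads of a gene and of an overlapping gene on the other strand cannot be told apart. Genes with near-identical copies, such as the globins, H2, Klr and Gbp families, and mitochondrial genes with nuclear copies, are uncertain where reads could be split between copies. Replicates were not repeats of one library: the chi-square per degree of freedom between replicates was at least 31.21, against 1 for sampling noise.

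Counts were analysed in R 4.3.3. With edgeR 4.0.16, genes were filtered by filterByExpr, leaving 22280, library sizes were scaled by TMM, and one mean per group was fitted over all 24 libraries (quasi-likelihood F test, robust, 16 residual degrees of freedom, common coefficient of biological variation 0.41). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were each treatment against vehicle on the same day, the combination against each single agent, its departure from the sum of the single agents on the log2 scale (non-additivity), the difference of each effect between days, and vehicle at day 3 against day 0. Log2 fold changes are those of edgeR's fit at its default prior count, and log2 CPM use a prior count of 2. Tumours taken as separate samples by the labels are the replicates. The p-values of single genes rest on the spread between them pooled over all 8 groups, not on that of the groups compared alone. Calls therefore change with only the groups compared, from 18 to 87 for D2C7-IT and vehicle at day 0 and from 9 to 0 for the combination and vehicle at day 3.

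The groups of genes were 36 lists fixed before the data were examined, as were the tests and the rule for naming genes. They cover signalling (CD40 and NF-kB, interferons, EGFR and MAPK feedback, stress, p53 and hypoxia), antigen presentation, cytokines, chemokines and complement, markers of immune, brain, vessel, blood and muscle cells, and cell cycle, mitochondrial, ribosomal and phagosome genes. Of their symbols, 2 are not in the tables. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list with all other genes, adjusted over the 36 lists of a comparison. The adjusted p with an estimated correlation, from the same test with the correlation measured in each list, served as an alternative. So did fry, which asks whether the members move one way on balance. Both were run only on all libraries at the main settings, so list calls under other settings use the preset correlation. The measured correlations ran from 0.04 in the alternative macrophage list to 0.96 in the cell cycle list. The preset takes members as nearly independent, so its p-values are too small where members move together and do not measure the spread between tumours. A gene adjusted over the list alone is one whose p passed when adjusted over the members of its list.

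Named genes follow one rule. For comparisons with vehicle it takes up to 6 called genes of highest and 6 of lowest log2 fold change, with at least 1 CPM on average in the higher group, no overlap between replicates and a symbol other than a predicted or clone name, and for other comparisons up to 5. It adds up to 4 members of smallest p from each list described, and Egfr, Cd40, Eef2, Cd274, Cd8a, Gzmb and Ifng. Where a group held 1 to 3 counts, a ratio of counts with an exact 95% interval is given, and where it held 0, a bound against 3 counts over the group. Both cover counting error only, the bound against 3 counts that of the empty group alone, since the reads carry no molecular identifiers.

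The edgeR step was tested on simulated counts for the comparison of D2C7-IT with vehicle at day 0 over 22280 genes. Of 50 genes each changed by 2, 4, 8 and 16 times, 4%, 58%, 92% and 100% were called, and 4 of the 135 calls were false. At a smaller dispersion than fitted, 80% of the changes of 2 times were called and 11 of 213 calls were false. Changes of 2 times in single genes were therefore mostly out of reach at the fitted spread. Genes were drawn independently, without the correlation between genes or the outlying libraries of the real data. The share of false calls therefore does not carry over to the real comparisons. Alternatives chosen in advance were DESeq2 1.42.0 (Wald test), its size factors in edgeR, no filter on counts, only the groups compared, the replicate number as a block, the mean of the neuron markers as a covariate, and leaving out each library. Log2 CPM of Egfr as a covariate and leaving out the 3 libraries of highest Egfr were added after the data were seen. Egfr is also the target of D2C7-IT. Adjusting for it, or leaving out libraries by it, therefore removes part of any effect on the amount of tumour.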

Results

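The series measured polyadenylated RNA in 24 mouse brain tumours, 3 in each of 8 groups. The tumours grew from CT-vIII, a line of the mouse glioma CT-2A that carries mouse EGFR variant III, a truncated growth factor receptor, and firefly luciferase. An osmotic pump infused the treatment straight into the brain for 72 h, from day 6 to day 9 after implantation. The treatments were a control solution (vehicle), the anti-CD40 antibody aCD40, the immunotoxin D2C7-IT, or both agents together. CD40 is a receptor that activates dendritic cells, macrophages and B cells. D2C7-IT joins an antibody fragment against EGFR and its variant to a part of Pseudomonas exotoxin, which halts protein synthesis by inactivating the elongation factor encoded by Eef2. Tumours were taken when the pumps came out (day 0) or 3 days later (day 3). Libraries held 24.7 to 48.1 M counted reads, with a median of 37.8 M. Below, levels are mean counts scaled to 1e6 per library (CPM) ± SD over the 3 tumours of a group. Gene fold changes are log2 ± SE from edgeR, and those of gene lists are the median over the members tested.

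Egfr, the gene that D2C7-IT targets, marked 3 of the day 3 tumours. Its reads come from the transgene and the mouse gene together (chromosome 11, 16752203 to 16918158). At day 0 its level was 28.5 ± 19.4 CPM in vehicle, 24.9 ± 17 in aCD40, 36.7 ± 9.66 in D2C7-IT and 18.2 ± 4.77 in the combination. At day 3 it was 213 ± 176, 122 ± 180, 23.8 ± 3.14 and 20.3 ± 2.27 CPM in the same order. The spread at day 3 came from 3 libraries: vehicle replicates 2 and 3 held 283 and 343 CPM and aCD40 replicate 1 held 330, while the other 21 libraries lay between 13.1 and 50.8. In these 3 libraries the cell cycle list averaged 6.43 to 6.71 log2 CPM, against 1.21 to 3.81 in the other 21. The neuron list averaged 6.83 to 7.62 against 8.53 to 9.11, the astrocyte list 5.93 to 6.84 against 7.10 to 8.13, and the oligodendrocyte list 4.73 to 6.41 against 5.80 to 8.08. The T cell list averaged 2.15 to 2.88 against -0.54 to 2.15. Microglia markers did not part them, at 5.04 to 5.49 against 4.70 to 5.59. Every day 0 library was among the 21 with low Egfr and high neuron levels. The share of tumour in them was not measured, so day 0 differences cannot be placed in tumour or in brain cells. The first principal component took 45.9% of the variance. Every comparison with vehicle or aCD40 at day 3 rests on these libraries. Leaving them out, an alternative chosen after the data were seen, leaves vehicle day 3 with 1 library, assumed to vary like the other groups. That library, replicate 1, held the lowest Egfr of all libraries (13.1 CPM).

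**Figure D1:**
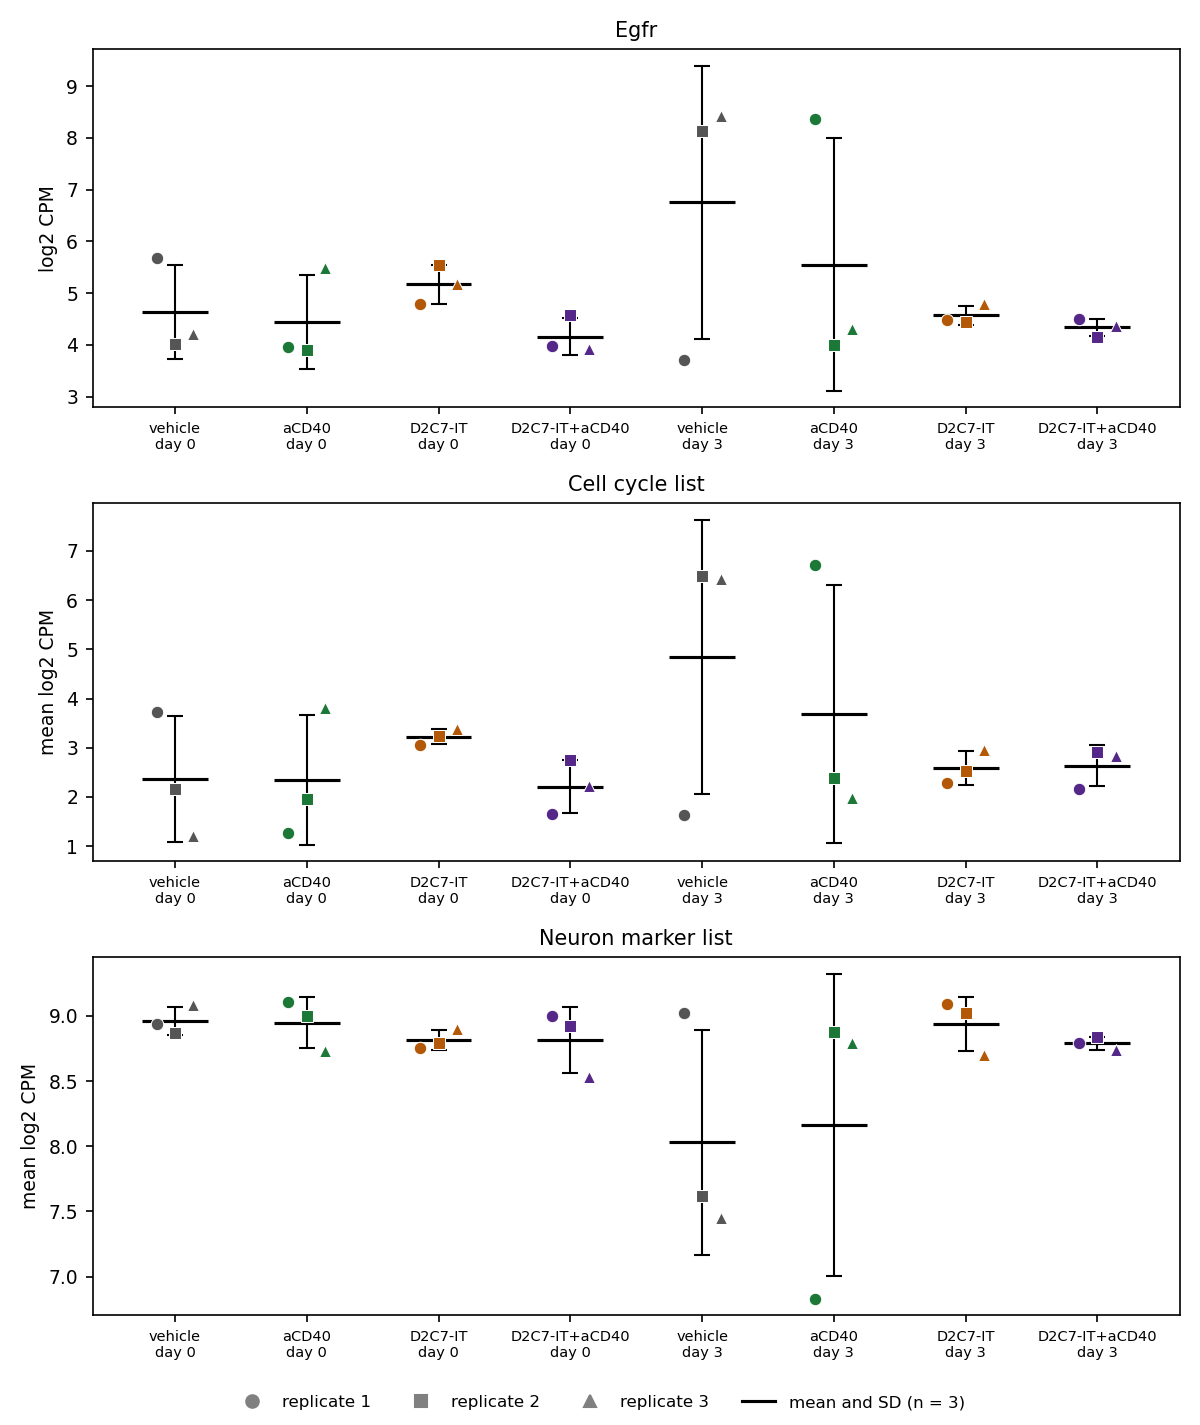
Level of Egfr and mean level of the cell cycle and neuron marker lists (log2 CPM) in each of the 24 libraries, by group, one point per tumour. Vehicle replicates 2 and 3 and aCD40 replicate 1 of day 3 lie above the others for Egfr (283 to 343 CPM against 13.1 to 50.8) and below them for neuron markers.

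Eef2, Cd40 and a few immune genes were followed in all groups. Eef2, the translation factor that the exotoxin inactivates, held 1350 ± 58.6, 1330 ± 59.7, 1240 ± 114 and 1280 ± 147 CPM at day 0 in vehicle, aCD40, D2C7-IT and the combination, and 1860 ± 485, 1780 ± 621, 1400 ± 29.7 and 1480 ± 47.2 at day 3. Cd40 held 1.23 ± 0.286, 2.56 ± 1.95, 8.88 ± 2.21 and 5.93 ± 4.92 CPM at day 0, and 7.98 ± 6.16, 15 ± 17.6, 1.46 ± 0.397 and 8.32 ± 2.62 at day 3. Cd274, which encodes the checkpoint ligand PD-L1, held 7.22 ± 3.7, 23.6 ± 22.9, 17.1 ± 1.7 and 39.7 ± 25.4 CPM at day 0, and 36.3 ± 25.6, 65.3 ± 64.8, 11.6 ± 1.23 and 59.2 ± 13.6 at day 3. Cd8a, a marker of cytotoxic T cells, held 0.96 ± 0.952, 3.04 ± 3.03, 1.53 ± 0.419 and 1.66 ± 1.69 CPM at day 0, and 10.9 ± 10.1, 10.6 ± 5.73, 1.32 ± 0.105 and 6.15 ± 2.53 at day 3. Gzmb, a protease of killer cells, held 1.39 ± 1.26, 3.51 ± 3.77, 1.34 ± 0.486 and 2.33 ± 1.17 CPM at day 0, and 20 ± 17.1, 17.4 ± 25.3, 0.87 ± 0.16 and 3.19 ± 1.31 at day 3. Ifng, the gene of interferon-gamma, stayed under 1 CPM on average in 6 groups and held 1.84 ± 1.62 in vehicle and 2.28 ± 2.93 in aCD40 at day 3. With Egfr, these 7 genes passed no comparison with vehicle in edgeR, where the smallest adjusted p was 0.08, for Ifng in D2C7-IT at day 3.

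At day 0, aCD40 tumours held more vessel and neutrophil transcripts and fewer red cell transcripts than vehicle tumours. The endothelial list rose by a median of 0.52, with all 15 members higher and 9 of them higher when adjusted over the list alone (camera adjusted p = 1.7e-35). Vwf, the platelet-binding factor of vessel walls, stood at 111 ± 11.6 CPM against 42.6 ± 7.69 (1.38 ± 0.23), and Cldn5, a tight junction protein of brain vessels, at 81.4 ± 12 against 41.1 ± 5.95. Pecam1, an adhesion molecule of endothelial cells, stood at 43.2 ± 5.37 against 23 ± 1.77. The edgeR adjusted p of these 3 genes was 0.063. The neutrophil list rose by 1.59, with 14 of 14 members higher, 2 of them adjusted over the list alone. S100a8, a calcium-binding protein of neutrophils, stood at 1.06 ± 0.288 CPM against 0.147 ± 0.0886. The erythroid list fell by 1.89, with 0 of 7 members higher and 5 lower when adjusted over the list alone. Hba-a1, an alpha globin gene with a near-identical copy, stood at 3.45 ± 0.581 CPM against 17.4 ± 13.4. With an estimated correlation the adjusted p was 3.3e-05 for the endothelial list and 0.0076 for the neutrophil and erythroid lists. By fry it was 3.8e-05 for the endothelial, 0.078 for the neutrophil and 0.07 for the erythroid list.

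Interferon and CD40-related genes were also higher on balance after aCD40 at day 0, a direction that depends on replicate 3 for several lists. The interferon-gamma list rose by 1.43 (23 of 24 members higher) and complement by 0.71 (14 of 14), with adjusted p = 0.78 and 0.45 with an estimated correlation. Gbp5, a guanylate-binding protein, had a log2 fold change of 1.59 ± 0.77, and C3, the central complement component, one of 2.23 ± 1.00. Type I interferon (0.56), MHC class I (0.97), T cell (0.45), cytotoxic (1.32), NK cell (1.02), regulatory T cell and checkpoint (0.51), B cell (0.86), monocyte (0.43), pattern recognition (0.41), cytokine (0.42), phagosome (0.36), and CD40 and NF-kB lists (0.38) were called too, each with adjusted p = 0.8 with an estimated correlation. In the last of these, Ccl22, a chemokine of activated dendritic cells, stood at 9.17 ± 5.63 CPM against 0.647 ± 0.24 (3.81 ± 0.75, edgeR adjusted p = 0.21). Ms4a1, which encodes CD20 of B cells, had 57 counts against 3, a ratio of 17.7 with a 95% counting interval of 5.74 to 88.1. The list of EGFR and MAPK feedback targets fell by 0.17, with adjusted p = 0.8 with an estimated correlation. In edgeR 0 genes passed, 303 had an unadjusted p under 0.05 and DESeq2 called 17. Without aCD40 replicate 3, 4 genes passed. Of the 18 list calls, 17, 13 and 9 held without vehicle replicate 1, 2 and 3, and 18, 17 and 5 without aCD40 replicate 1, 2 and 3, those held throughout being interferon-gamma, complement, neutrophil, endothelial and erythroid. Without aCD40 replicate 3 the medians were 0.30 for interferon-gamma, 0.21 for complement and 0.89 for neutrophil lists, and they turned to -0.10 for CD40 and NF-kB, -0.12 for type I interferon, NK cell and phagosome, -0.11 for B cell, -0.13 for checkpoint, -0.25 for monocyte, -0.21 for pattern recognition, -0.14 for cytokine and -0.05 for T cell lists. Without vehicle replicate 3 the erythroid median was -1.03.

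After D2C7-IT at day 0, genes that draw in and mark neutrophils rose, and 18 genes passed in edgeR, all higher. Cxcl2 and Cxcl1, chemokines that recruit neutrophils, stood at 16.8 ± 5.32 and 57.2 ± 17.1 CPM against 0.0305 ± 0.0264 and 0.257 ± 0.107 in vehicle (9.00 ± 1.61 and 7.74 ± 1.30, edgeR adjusted p = 0.045 and 0.033). Both lie on chromosome 5, at 90903871 to 90905938 and 90891241 to 90893115. Their receptor Cxcr2 (5.99 ± 1.09) and the neutrophil proteins S100a8 (3.76 ± 0.64) and S100a9 (3.10 ± 0.56) rose as well, with edgeR adjusted p = 0.045, 0.035 and 0.045. Other genes that passed were Mmp3, a matrix protease (7.74 ± 1.08), Steap4, an iron and copper reductase (134 ± 5.95 CPM against 0.865 ± 0.503), Fas, a death receptor (20.1 ± 3.8 against 2.51 ± 0.223), and Vwf (125 ± 7.67 against 42.6 ± 7.69), with edgeR adjusted p = 0.011, 0.031, 0.045 and 0.021. Vehicle held 3 counts each of Cxcl2, Mmp3 and Cxcr2, and the ratios were 612, 255 and 72.3, with 95% counting intervals of 209 to 2970, 87 to 1240 and 24.5 to 353. Outside the rule for naming genes, and chosen after their values were seen, were Angptl4, a regulator of lipoprotein lipase (3.52, edgeR adjusted p = 0.0047), Mt2, a metallothionein (1.65), and Osmr, the receptor of oncostatin M (2.15).

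By list, the neutrophil markers rose by 2.22 after D2C7-IT at day 0 (14 of 14 members higher, 3 called over all genes and 7 adjusted over the list alone), chemokines by 1.53 (2 called and 6 adjusted over the list alone) and endothelial markers by 0.34 (1 called and 6 adjusted over the list alone). Their camera adjusted p was 1e-17, 1.6e-12 and 6.2e-12, and 0.0083, 0.029 and 0.0098 with an estimated correlation. Ccl2, which draws in monocytes, stood at 103 ± 22.7 CPM against 2.26 ± 2.13 (5.49 ± 1.32, edgeR adjusted p = 0.2). The CD40 and NF-kB list rose by 1.56, with 22 of 22 members higher and 11 adjusted over the list alone, and pro-inflammatory cytokines by 1.52, with 8 adjusted over the list alone. These calls had adjusted p = 0.13 and 0.063 with an estimated correlation. Among their members, the adhesion molecule Icam1 stood at 123 ± 47.6 CPM against 8.52 ± 5.45, Tnfaip3, which restrains NF-kB, at 89.8 ± 32.6 against 10 ± 3.75, and Il6 at 4.11 ± 1.91 against 0.0384 ± 0.0358 (edgeR adjusted p = 0.11, 0.16 and 0.069). The type I interferon list rose with 24 of 24 members higher, monocyte and macrophage markers by 1.07, pattern recognition by 0.94, complement by 0.79 and p53 and apoptosis genes by 0.43, with adjusted p = 0.31, 0.36, 0.36, 0.25 and 0.36 with an estimated correlation. Mx2, an antiviral GTPase, had a log2 fold change of 2.73 ± 0.78, and Gdf15, a stress-induced cytokine, one of 4.95 ± 1.12.

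Weaker list calls after D2C7-IT at day 0 were interferon-gamma (0.81, adjusted p = 0.69 with an estimated correlation), and MHC class I (0.50), NK cell (1.08), cell cycle (0.40), phagosome (0.35), and integrated and ER stress lists (0.04), each with adjusted p = 0.77 with an estimated correlation. In the stress list 9 of 18 members were higher, among them Ppp1r15a, which restarts translation after stress, at 54.1 ± 14.7 CPM against 15.2 ± 1.42. Microglia (0.13), dendritic cell (0.46), pericyte and fibroblast (-0.04), skeletal muscle (-0.25), ribosomal protein (-0.02), hypoxia (0.02) and oligodendrocyte lists (0.15) were not called. DESeq2 called 133 genes, and 1007 had an unadjusted p under 0.05. Without vehicle replicate 1 or 3, 0 genes passed in edgeR, without vehicle replicate 2 it was 1, and without each D2C7-IT replicate it was 2. Of the 16 list calls, 16, 14 and 12 held without vehicle replicate 1, 2 and 3, and 15, 15 and 14 without D2C7-IT replicate 1, 2 and 3, those that ended being MHC class I, NK cell, cell cycle, stress and phagosome.

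After the combination at day 0, vessel transcripts were higher and red cell and alternative macrophage transcripts lower than in vehicle. The endothelial list rose by 0.50 (15 of 15 members higher, 9 adjusted over the list alone), with Cldn5 at 77.6 ± 3.37 CPM against 41.1 ± 5.95. The erythroid list fell by 1.73 (0 of 7 higher, 6 lower when adjusted over the list alone). The list of alternative macrophage activation fell by 0.74, with 5 of 15 members higher and 1 lower when adjusted over the list alone. In it, Clec10a, a lectin of macrophages and dendritic cells, stood at 0.688 ± 0.0747 CPM against 1.65 ± 0.292, and Mrc1, the mannose receptor, at 3.59 ± 0.677 against 7.44 ± 1.34. With an estimated correlation the adjusted p was 0.00087 for the endothelial list and 0.043 for the other lists. Interferon-gamma (1.68), type I interferon (1.06), MHC class I (1.00), cytokine (1.02), and CD40 and NF-kB lists (0.81) rose as well, with adjusted p = 0.34, 0.55, 0.57, 0.32 and 0.55 with an estimated correlation. Ccl22 stood at 6.32 ± 1.69 CPM against 0.647 ± 0.24, and Tap2, the peptide transporter of class I presentation, at 63.9 ± 27.9 against 21.7 ± 8.46.

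The other lists called after the combination at day 0 were neutrophil (0.90), chemokine (0.53), complement (0.61), cytotoxic (0.75), pattern recognition (0.38), EGFR and MAPK feedback (-0.29) and mitochondrially encoded genes (-0.26), with adjusted p = 0.21, 0.4, 0.57, 0.83, 0.83, 0.83 and 0.83 with an estimated correlation. Cxcl2 had 398 counts against 3, a ratio of 117 with a 95% counting interval of 39.6 to 568. In edgeR 0 genes passed, 675 had an unadjusted p under 0.05 and DESeq2 called 26. Of the 15 list calls, 14, 14 and 11 held without vehicle replicate 1, 2 and 3, and 14, 11 and 13 without combination replicate 1, 2 and 3. The endothelial, erythroid, alternative macrophage, interferon, MHC class I, cytokine, neutrophil, and CD40 and NF-kB calls held throughout, at smaller medians in places. The alternative macrophage median was -0.18 without vehicle replicate 1 and the erythroid one -0.90 without vehicle replicate 3. Without combination replicate 2, CD40 and NF-kB stood at 0.17 and cytokines at 0.52.

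**Figure D2:**
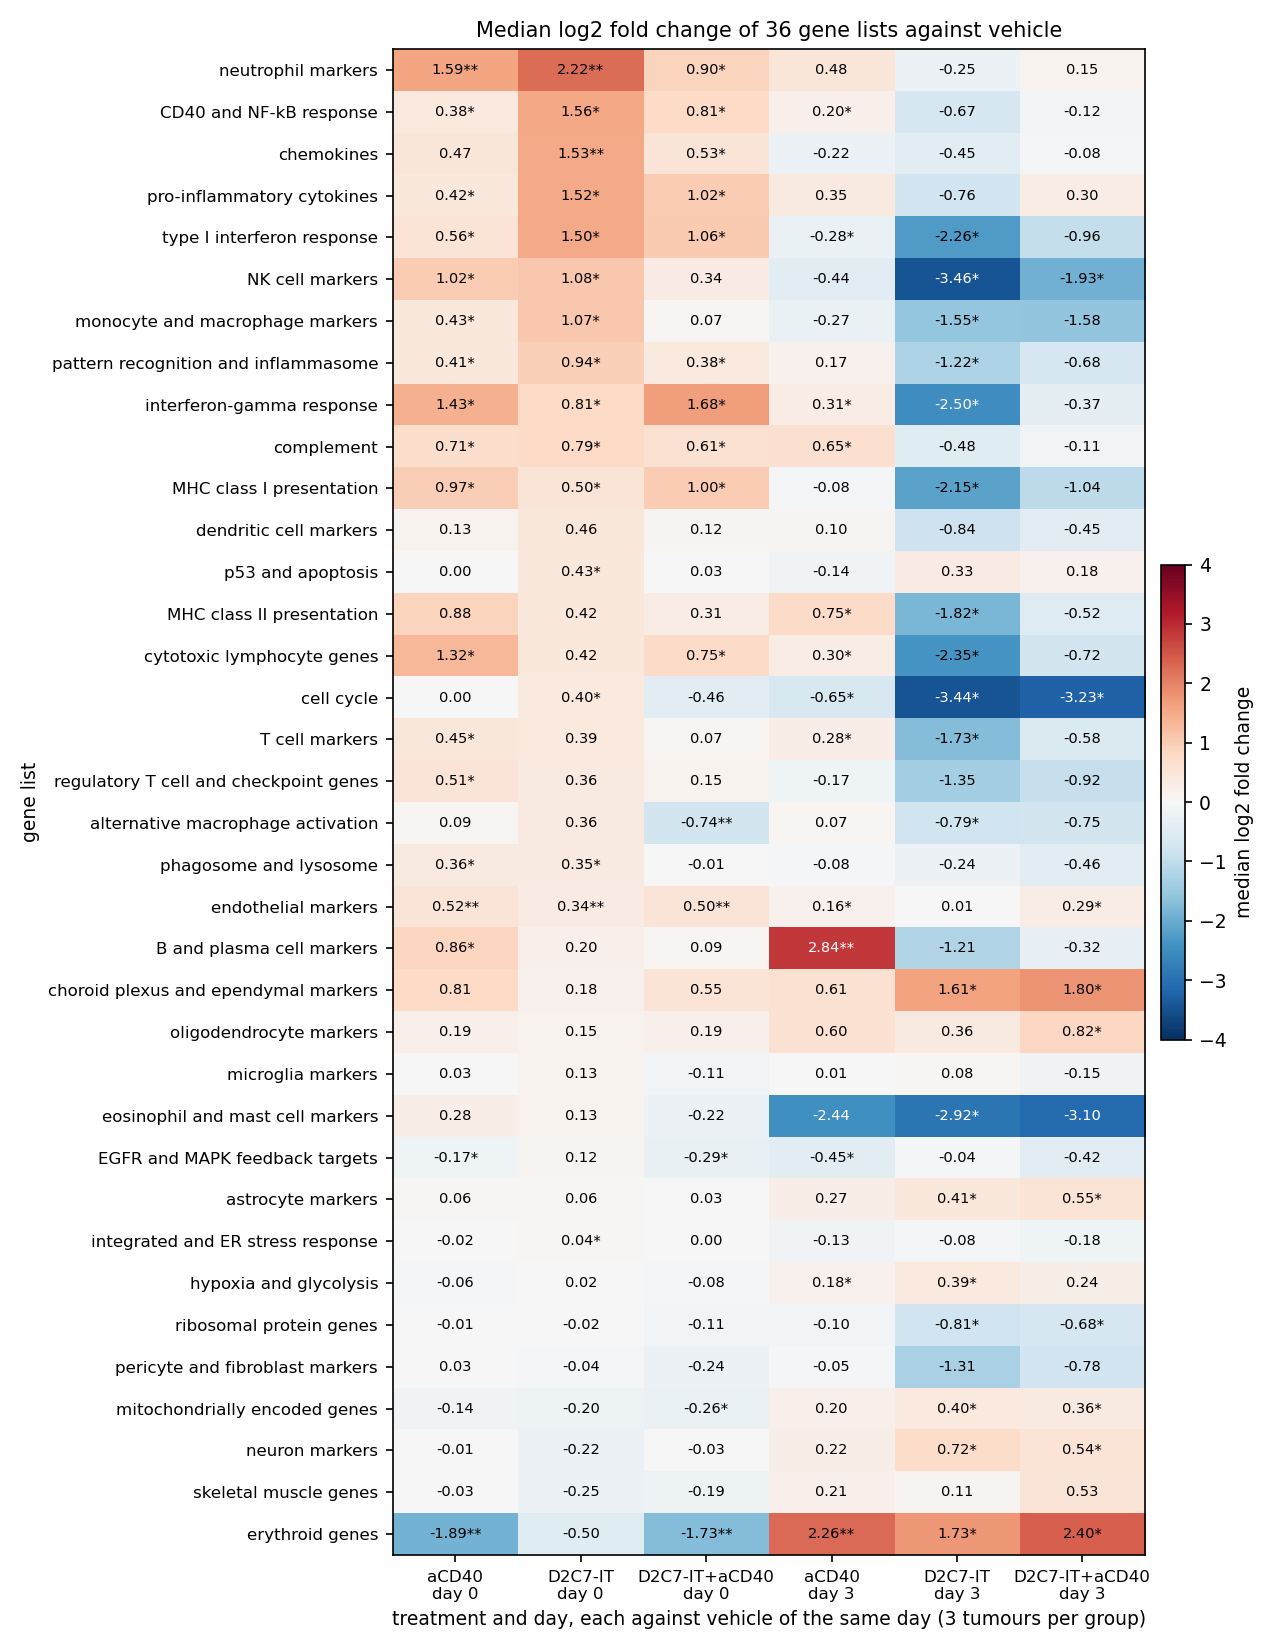
Median log2 fold change of each of the 36 gene lists (one per line) in the 6 comparisons with vehicle (columns), as colour. An asterisk marks a list called by camera with its preset correlation, and a pair of asterisks one also called with an estimated correlation.

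Set against the single agents at day 0, the combination differed most clearly, by camera, in the list of alternative macrophage activation. The alternative macrophage list fell by 0.93 against aCD40, with 0 of 15 members higher, and by 0.97 against D2C7-IT, with 3 lower when adjusted over the list alone. With an estimated correlation the adjusted p was 0.0043 and 0.0022. By fry the adjusted p against aCD40 was 0.3, and fry called 0 lists in that comparison. Without aCD40 replicate 3 the first median was -0.54. F13a1, a transglutaminase of macrophages and platelets, stood at 4.27 ± 1.69 CPM in the combination against 23.7 ± 9.79 in D2C7-IT (-2.47 ± 0.55, edgeR adjusted p = 0.69). Of 14 lists called against aCD40, 5 were higher and 9 lower, and of 20 called against D2C7-IT, 2 were higher and 18 lower. Against D2C7-IT, neutrophil (-1.28), monocyte (-1.04), chemokine (-1.12), and p53 and apoptosis lists (-0.49) were among those that fell, with adjusted p = 0.069, 0.62, 0.14 and 0.37 with an estimated correlation. Examples were Cxcr2 at 0.211 ± 0.269 CPM against 1.99 ± 0.505, Ccr2, the monocyte receptor of Ccl2, at 3.16 ± 1.36 against 15.3 ± 1.69, and Fas at 6.91 ± 5.5 against 20.1 ± 3.8. The EGFR and MAPK feedback list fell by 0.47 against D2C7-IT, with adjusted p = 0.37 with an estimated correlation, and Hbegf, an EGFR ligand, stood at 12 ± 4.02 CPM against 50.6 ± 10.9. In edgeR 0 genes passed in either comparison, where 197 and 617 had an unadjusted p under 0.05, and DESeq2 called 6 against aCD40 and 20 against D2C7-IT.

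The combination also departed from the sum of the single agents at day 0. Tested as the combination effect less both single effects, neutrophil markers departed by a median of -2.81 (0 of 14 members higher), alternative macrophage genes by -1.11 and endothelial markers by -0.48. Members lower when adjusted over the list alone were 4, 1 and 4, and the adjusted p with an estimated correlation was 0.0021, 0.0033 and 0.0033. For S100a8 the departure was -3.94 ± 0.84 (edgeR adjusted p = 0.93), for Arg1, an arginine-degrading enzyme of macrophages, -6.84 ± 2.29, and for Vwf -1.85 ± 0.32 (edgeR adjusted p = 0.31). The effects at day 0 share the same 3 vehicle tumours, so a low vehicle level (4.50 log2 CPM on the endothelial list, against 5.11, 4.93 and 5.02 in aCD40, D2C7-IT and the combination) would raise each of them and lower the departure. In all, 22 lists lay below additivity and 0 above, 3 of them with an estimated correlation as well. In edgeR 0 genes passed, 360 had an unadjusted p under 0.05 and DESeq2 called 5. Without combination replicate 2, 4 genes passed, all lower.

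**Figure D3:**
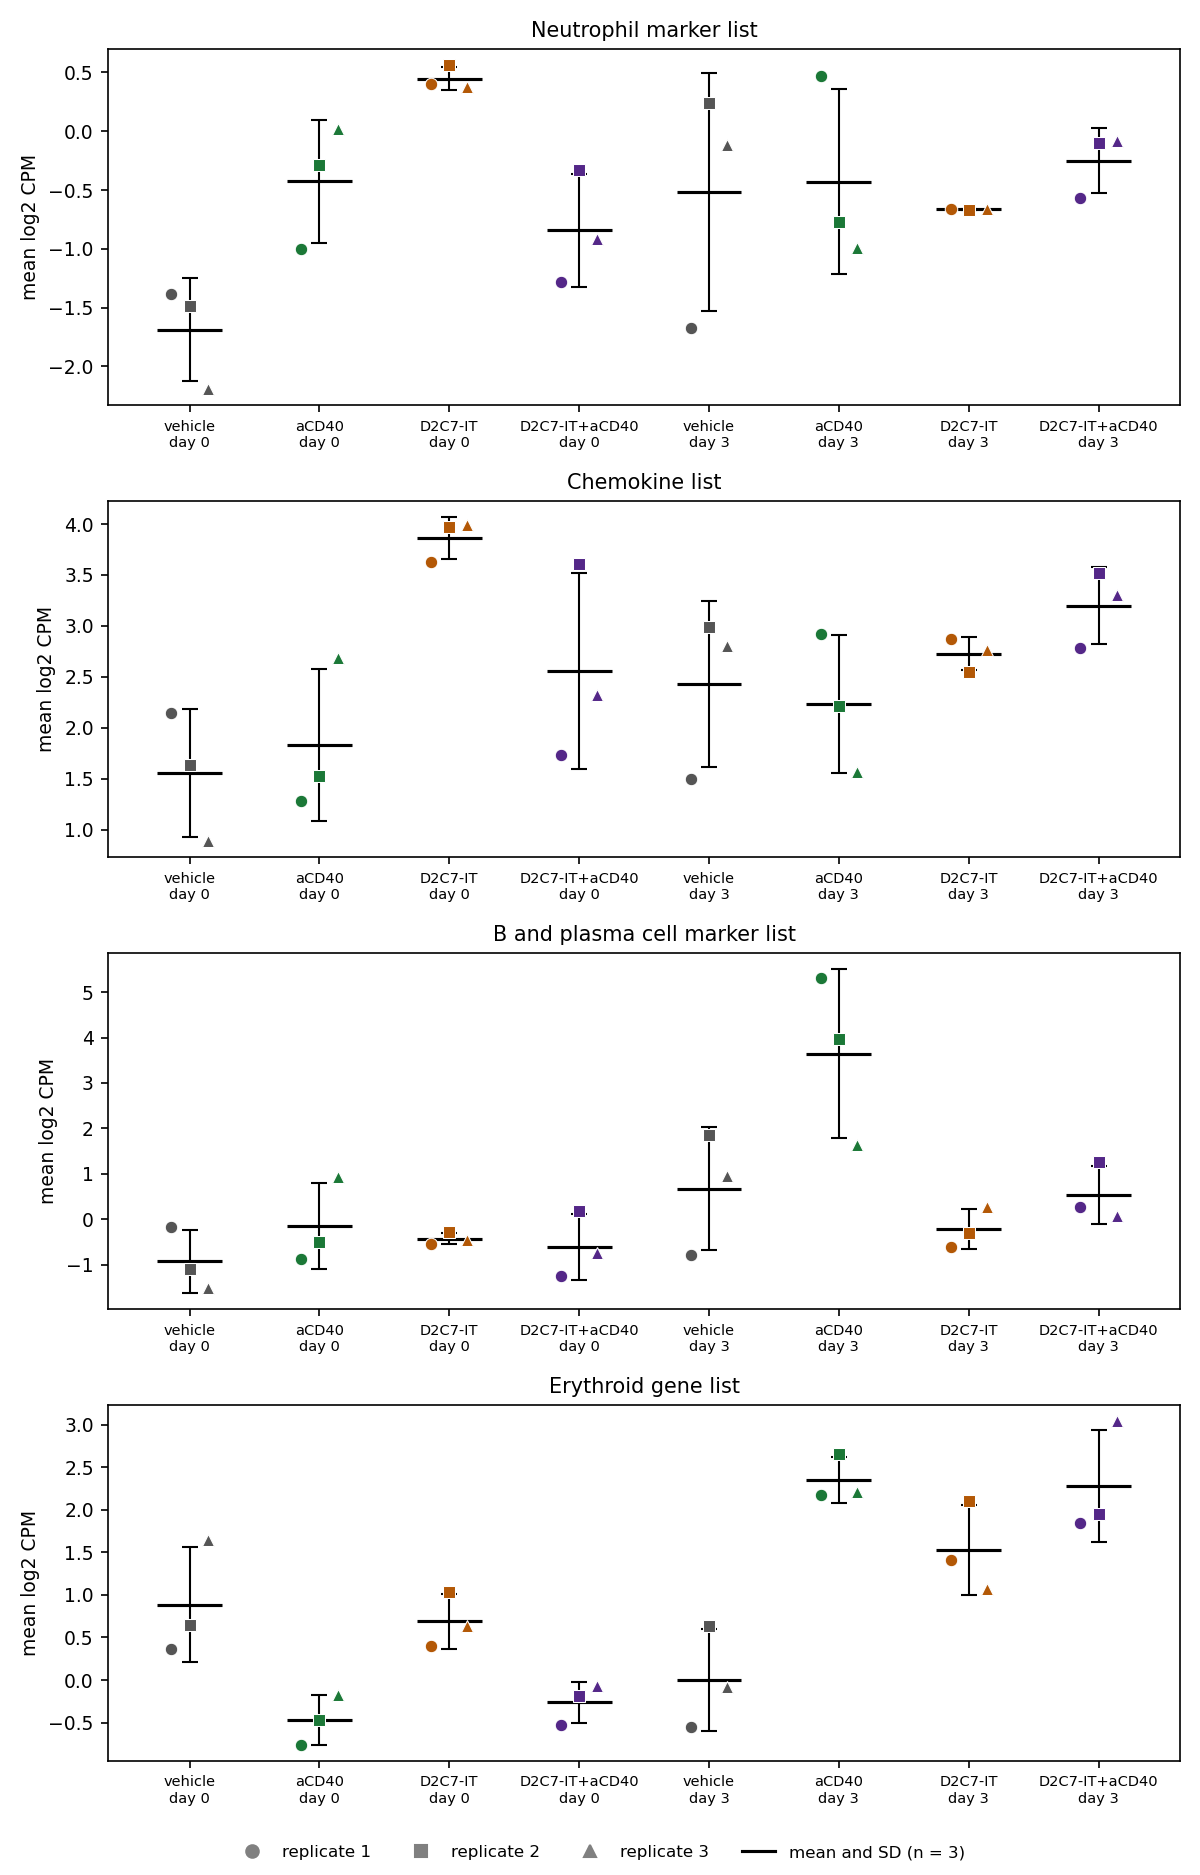
Mean level (log2 CPM) of the neutrophil, chemokine, B and plasma cell, and erythroid lists in each of the 24 libraries, by group, one point per tumour. Neutrophil and chemokine levels are high in D2C7-IT at day 0, B cell levels in aCD40 at day 3, and erythroid levels are lower with aCD40 at day 0 than at day 3.

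Vehicle tumours themselves differed between the days, with immune and dividing cell transcripts higher at day 3 in replicates 2 and 3. The type I interferon list rose by 2.59 (24 of 24 members higher, all 24 adjusted over the list alone), interferon-gamma by 2.70 (22 adjusted over the list alone), NK cell markers by 3.55 (13 of 13), cell cycle genes by 3.32 (24 of 24) and ribosomal protein genes by 0.87 (19 of 22 adjusted over the list alone). Eosinophil and mast cell markers rose by 4.06, and neuron markers fell by 0.80. Each of these 24 list calls had adjusted p = 0.51 with an estimated correlation. Ifi47, an interferon-inducible GTPase, stood at 91.6 ± 75.9 CPM against 8.2 ± 5.54, Mcm6, a subunit of the replicative helicase, at 106 ± 81.4 against 12.8 ± 6.77, Cma1, a mast cell protease, at 4.54 ± 4.28 against 0.0474 ± 0.0221, and Camk2a, a kinase of excitatory neurons, at 1250 ± 798 against 2910 ± 1220. 0 genes passed in edgeR, 6720 had an unadjusted p under 0.05 and DESeq2 called 2425. Without vehicle day 3 replicate 1, 9451 genes passed. Without the 3 libraries of highest Egfr, the cell cycle list stood at -1.29, NK cell at -0.79, interferon-gamma at -0.53 and type I interferon at 0.18.

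At day 3, aCD40 tumours held more B cell and red cell transcripts than vehicle tumours. The B and plasma cell list rose by 2.84, with 18 of 18 members higher and 15 adjusted over the list alone (camera adjusted p = 1.3e-43). Cd79a, a subunit of the B cell receptor, stood at 27.2 ± 27 CPM against 1.43 ± 0.984, Ms4a1 at 25.8 ± 24.1 against 0.599 ± 0.498, Bank1, a B cell scaffold, at 10.2 ± 8.64 against 1.07 ± 0.489, and Fcer2a, the IgE receptor CD23, at 7.1 ± 5.32 against 0.616 ± 0.365, with edgeR adjusted p = 0.097, 0.22, 0.083 and 0.083. The erythroid list rose by 2.26 (7 of 7, all 7 adjusted over the list alone, camera adjusted p = 2.8e-31), and Hba-a1 had a log2 fold change of 2.26 ± 0.48 (edgeR adjusted p = 0.29). For the B cell and erythroid lists the adjusted p was 0.0093 and 0.00081 with an estimated correlation. Both calls held without each library, the B cell median ranging from 1.93 to 3.90 over the alternatives and the erythroid one from 2.06 to 3.09, highest at 3.90 and 3.09 without the 3 libraries of highest Egfr. The MHC class II list rose by 0.75 (11 of 11, 3 adjusted over the list alone), with adjusted p = 0.57 with an estimated correlation, and its median was 3.73 without those 3 libraries. The class II call ended without vehicle replicate 1 and without aCD40 replicate 1, where its median was -0.31. Its H2-Ob and H2-Oa, which B cells use to tune class II loading, had log2 fold changes of 3.20 ± 0.66 and 2.67 ± 0.67 (edgeR adjusted p = 0.25 and 0.56).

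Other lists called after aCD40 at day 3 differed by less than 1 at the median with all libraries. They were T cell (0.28), cytotoxic (0.30), interferon-gamma (0.31), CD40 and NF-kB (0.20), complement (0.65), endothelial (0.16), hypoxia (0.18), type I interferon (-0.28), cell cycle (-0.65) and EGFR and MAPK feedback (-0.45). The adjusted p with an estimated correlation was 0.86, 0.86, 0.92, 0.92, 0.86, 0.62, 0.86, 0.92, 0.86 and 0.81. Spry4, a MAPK feedback inhibitor, stood at 16.9 ± 6.3 CPM against 24.1 ± 9.25, and Mcm4, another helicase subunit, at 47.9 ± 62.9 against 74.9 ± 55.2. Choroid plexus and ependymal (0.61), NK cell (-0.44) and neutrophil markers (0.48) were not called. 0 genes passed in edgeR, 425 had an unadjusted p under 0.05 and DESeq2 called 35. Without aCD40 replicate 1, 1364 genes passed (82 higher and 1282 lower) and the medians were -3.78 for cell cycle and -2.36 for type I interferon lists, and without aCD40 replicate 3 it was 23. Of the 13 list calls, 5, 11 and 10 held without vehicle replicate 1, 2 and 3, and 5, 11 and 11 without aCD40 replicate 1, 2 and 3. Without the 3 libraries of highest Egfr the cell cycle median turned to 0.61, the type I interferon (-0.05), EGFR and MAPK feedback (-0.11) and hypoxia (0.02) calls ended, and the T cell, cytotoxic and interferon-gamma medians were 2.28, 2.83 and 1.98.

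With all libraries, D2C7-IT tumours at day 3 held fewer immune and dividing cell transcripts than vehicle tumours and more brain, red cell and hypoxia transcripts. Most of the immune, dividing cell and brain differences turned without the 3 libraries of highest Egfr, as the next paragraph gives. Vehicle is then replicate 1 alone, with the lowest Egfr of all libraries (13.1 CPM). The omission also selects by Egfr, so it cannot tell a treatment effect from outlying tumours. Cell cycle genes fell by 3.44 (24 of 24 members lower, all 24 adjusted over the list alone), NK cell markers by 3.46 (13 of 13), cytotoxic genes by 2.35 (9 adjusted over the list alone), type I interferon genes by 2.26 (22), MHC class I genes by 2.15 (16) and ribosomal protein genes by 0.81 (19). Interferon-gamma genes fell as well, 16 adjusted over the list alone. Each had adjusted p = 0.7 with an estimated correlation. Prf1, the pore protein of killer cells, stood at 0.265 ± 0.246 CPM against 4.85 ± 4.03, Tgtp2, an interferon-inducible GTPase, at 2.85 ± 1.55 against 75 ± 63.2, H2-Eb1, a class II chain, at 20.1 ± 13.9 against 196 ± 164, and Plk1, a mitotic kinase, at 4.29 ± 1.13 against 46.9 ± 38.3. Slc2a1, the glucose transporter GLUT1, stood at 167 ± 52.1 CPM against 84.3 ± 12.1 (0.98 ± 0.17, edgeR adjusted p = 0.066), and Adm, a hypoxia-induced vasodilator, at 10.4 ± 8.65 against 2.2 ± 0.579. The erythroid list rose by 1.73 (7 of 7, 6 adjusted over the list alone), neuron markers by 0.72 (17 of 17), choroid plexus and ependymal markers by 1.61, and hypoxia and glycolysis genes by 0.39, each with adjusted p = 0.7 with an estimated correlation.

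Further lists called after D2C7-IT at day 3 were MHC class II (-1.82), T cell (-1.73), monocyte (-1.55), pattern recognition (-1.22), alternative macrophage (-0.79), eosinophil and mast cell (-2.92), astrocyte (0.41) and mitochondrially encoded genes (0.40). The adjusted p with an estimated correlation was 0.77 for class II, monocyte, pattern recognition, astrocyte and mitochondrial lists, and 0.7 for the rest. Cpa3, a mast cell protease, stood at 0.115 ± 0.0792 CPM against 4.14 ± 3.69, Ly6c2 of inflammatory monocytes at 1.34 ± 0.953 against 42.7 ± 36.2, and Aldh1l1, an astrocyte enzyme, at 89.2 ± 12.2 against 52.5 ± 7.36. 0 genes passed in edgeR, 6287 had an unadjusted p under 0.05, and DESeq2 called 2790 (844 higher and 1946 lower). Without vehicle replicate 1, which has low Egfr, 8203 genes passed, and without D2C7-IT replicate 3 it was 430. Of the 19 list calls, 18, 13 and 12 held without vehicle replicate 1, 2 and 3, and 17, 18 and 15 without D2C7-IT replicate 1, 2 and 3. Without the 3 libraries of highest Egfr the medians were 0.98 for cell cycle, 0.86 for NK cell, 1.24 for cytotoxic, 0.50 for interferon-gamma, 0.68 for MHC class I, 0.14 for ribosomal protein and -0.02 for neuron lists. They were 1.08 for MHC class II, 0.88 for T cell, 0.78 for monocyte, 1.07 for pattern recognition, 0.64 for eosinophil and mast cell, -0.16 for astrocyte and -0.23 for mitochondrial lists, and the type I interferon, alternative macrophage and choroid plexus calls ended at 0.08, 0.40 and 1.69. The choroid plexus call also ended without D2C7-IT replicate 2 (0.79), and the hypoxia call without vehicle replicate 1, without D2C7-IT replicate 1 and with only the groups compared. With the preset correlation, the erythroid call held under all 13 alternatives of settings and libraries. It was lost with an estimated correlation (adjusted p = 0.7).

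At day 3, 9 genes were called higher in the combination than in vehicle in edgeR. With only the groups compared 0 genes passed, and with neuron markers as a covariate 2 did. Slc2a1 stood at 174 ± 9.45 CPM against 84.3 ± 12.1 (1.05 ± 0.17), Acer2, an alkaline ceramidase, at 29.5 ± 1.24 against 8.61 ± 2.97 (1.78 ± 0.26), Epb42, a red cell membrane protein, at 2.65 ± 1.69 against 0.0762 ± 0.00574 (5.06 ± 0.81), and Myo15, an unconventional myosin, at 5.37 ± 3.01 against 0.303 ± 0.108 (4.13 ± 0.64), each with edgeR adjusted p = 0.026. Aloxe3, a lipoxygenase, stood at 33.1 ± 15.8 CPM against 3.24 ± 2.49 (edgeR adjusted p = 0.045). Ddit3, the stress transcription factor CHOP, stood at 59.9 ± 22.9 against 23.7 ± 0.771 (edgeR adjusted p = 0.031), but it overlaps Mars on the opposite strand, which holds 169% of its counts, and the library kit does not mark strand. Psca, a surface antigen, stood at 1.99 ± 2.01 CPM against 0, with an SD as large as its mean. It had 240 counts against 0, at least 80.4-fold higher against a floor of 3 counts over the group. The lower 95% counting limit was 64.9 once error in the 240 is included, and the spread between tumours is not covered. Usp53 (0.83, edgeR adjusted p = 0.045) and Gm11274 (3.51, edgeR adjusted p = 0.026) complete the 9 and were chosen after their values were seen. Slc2a1 spans 119108711 to 119137983 and Acer2 86874396 to 86934822, both on chromosome 4.

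By list, the combination at day 3 was higher than vehicle in erythroid genes (2.40, 7 of 7, all 7 adjusted over the list alone), choroid plexus and ependymal markers (1.80, 11 of 11), endothelial markers (0.29, 14 of 15), and oligodendrocyte (0.82), astrocyte (0.55), neuron (0.54) and mitochondrially encoded genes (0.36). Cell cycle genes fell by 3.23 (24 of 24 adjusted over the list alone), NK cell markers by 1.93 and ribosomal protein genes by 0.68. The adjusted p with an estimated correlation was 0.22 for the erythroid list, 0.77 for the endothelial list and 0.91 for each of the rest. Hba-a1 had a log2 fold change of 2.40 ± 0.49 (edgeR adjusted p = 0.082), Foxm1, a regulator of mitosis, stood at 4.71 ± 0.662 CPM against 112 ± 94.9, and Ttr, the choroid plexus transport protein transthyretin, at 306 ± 265 against 1.01 ± 0.429. Opalin of myelin stood at 28.8 ± 8.7 CPM against 11 ± 7.67. DESeq2 called 1642 genes, and 5352 had an unadjusted p under 0.05. Without vehicle replicate 1, 6925 genes passed in edgeR, without combination replicate 1 it was 122, and without vehicle replicate 2 or 3, or combination replicate 2 or 3, it was 0. Of the 10 list calls, 10, 8 and 8 held without vehicle replicate 1, 2 and 3, and 8, 10 and 9 without combination replicate 1, 2 and 3. With the 3 libraries of highest Egfr left out, 0 genes passed, the medians were 1.20 for cell cycle, 2.53 for NK cell -0.20 for neuron, 0.03 for astrocyte, -0.21 for mitochondrial and 0.28 for ribosomal protein lists, the oligodendrocyte call ended at 0.33, and the endothelial, choroid plexus and erythroid calls held.

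Against aCD40 at day 3, the combination held fewer B cell transcripts. The B and plasma cell list fell by 3.60 (18 of 18 lower, all 18 adjusted over the list alone) and MHC class II by 1.97 (3 adjusted over the list alone), with adjusted p = 0.19 and 0.77 with an estimated correlation. Bank1 stood at 0.882 ± 0.115 CPM against 10.2 ± 8.64 (-3.53 ± 0.55, edgeR adjusted p = 0.052) and Cd79a at 2.14 ± 1.31 against 27.2 ± 27. With the preset correlation, both list calls held without each library. Cell cycle genes fell by 2.53 and ribosomal protein genes by 0.61, each with adjusted p = 0.77 with an estimated correlation, and both calls ended without aCD40 replicate 1, where the cell cycle median was 0.45. Without the 3 libraries of highest Egfr it was 0.46, and the MHC class II median was -0.85. Of 14 lists called, 6 were higher and 8 lower, and 0 were called with an estimated correlation. Those higher were chemokine, neuron, astrocyte, oligodendrocyte, choroid plexus and mitochondrial lists. By gene, edgeR passed 0, 2469 had an unadjusted p under 0.05 and DESeq2 called 205. Without combination replicate 1, 88 genes passed, and without aCD40 replicate 3 it was 30.

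Against D2C7-IT at day 3, the combination held more interferon, killer cell and antigen presentation transcripts, a comparison that uses none of the 3 libraries of highest Egfr. The interferon-gamma list rose by 2.15 (23 of 24 higher, 10 adjusted over the list alone), cytotoxic genes by 1.87 (17 of 17, 3 adjusted over the list alone), NK cell markers by 1.55, type I interferon genes by 1.36, MHC class II by 1.18, MHC class I by 1.07, CD40 and NF-kB by 0.47 and endothelial markers by 0.42 (4 adjusted over the list alone). The adjusted p with an estimated correlation was 0.016 for the endothelial list, 0.25 for interferon-gamma and cytotoxic genes, 0.52 for CD40 and NF-kB, and 0.38 for the rest. Ccl22 stood at 21.1 ± 10.1 CPM against 1.46 ± 0.772, Serpina3g, an interferon-induced serpin, at 7.91 ± 1.91 against 0.683 ± 0.421, and Ifng at 0.76 ± 0.434 against 0.0338 ± 0.00646. Tie1, a receptor of endothelial cells, stood at 17.6 ± 1.44 CPM against 12.5 ± 2.06. With the preset correlation, these 8 list calls held without each library, CD40 and NF-kB at 0.20 without combination replicate 2. The estimated correlation was not run without them. In all, 20 lists were called, 19 higher and 1 lower, and 1 was called with an estimated correlation as well. 0 genes passed in edgeR, at a smallest adjusted p of 1, 544 had an unadjusted p under 0.05 and DESeq2 called 3.

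With the preset correlation, the combination at day 3 lay above the sum of the single agents in interferon genes and below it in red cell and B cell genes. Of 14 lists called, 11 lay above and 3 below, and 0 were called with an estimated correlation. The erythroid list departed by -1.66 (0 of 7 higher, 3 lower when adjusted over the list alone, adjusted p = 0.08 with an estimated correlation), ranging from -2.47 to -1.26 over the alternatives. The departure was 1.57 for the type I interferon list (24 of 24 members higher), 1.78 for interferon-gamma and -2.25 for B and plasma cell markers (0 of 18 higher, 3 lower when adjusted over the list alone). For these 3 lists the adjusted p was 0.63, 0.8 and 0.22 with an estimated correlation, and the interferon-gamma call ended without the 3 libraries of highest Egfr. Without aCD40 day 3 replicate 1 alone, their departures were 3.79, 3.55 and -1.24. Iigp1, an interferon-inducible GTPase, departed by 3.08 ± 1.48 and Fcer2a by -3.38 ± 0.77. The effects share the same vehicle tumours, so a high vehicle level would raise the departure and a low one would lower it. Vehicle stood at 5.62 ± 1.64 log2 CPM on the type I interferon list, against 4.86, 3.84 and 5.13 in aCD40, D2C7-IT and the combination. On the erythroid list it stood at -0.00 ± 0.59, against 2.35, 1.53 and 2.28. By gene, edgeR passed 0, 251 had an unadjusted p under 0.05 and DESeq2 called 0. Without aCD40 replicate 3, 1 gene passed.

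Treatment effects differed between the days most clearly in red cell genes. The erythroid effect of aCD40 was 4.35 higher at day 3 than at day 0 (7 of 7 members, 6 adjusted over the list alone) and that of the combination 4.12 higher (7 of 7, all 7 adjusted over the list alone), with adjusted p = 1e-04 and 0.017 with an estimated correlation. Hba-a1 differed by 4.59 ± 0.69 and 4.12 ± 0.68, with edgeR adjusted p = 0.058 and 0.19. The endothelial effect of aCD40 was lower at day 3 by a median of -0.45 (5 adjusted over the list alone, adjusted p = 0.0097 with an estimated correlation) and its B cell effect higher by 2.35 (adjusted p = 0.13 with an estimated correlation). For D2C7-IT the type I interferon effect differed by -3.73, that on neutrophil markers by -2.42 and that on cell cycle genes by -3.98, with adjusted p = 0.43, 0.28 and 0.46 with an estimated correlation. For the combination, type I interferon differed by -2.04 and cell cycle by -2.75, each with adjusted p = 0.9 with an estimated correlation. Without the 3 libraries of highest Egfr the cell cycle differences became 0.71 for D2C7-IT and 1.76 for the combination, those of type I interferon -1.43 and 0.27, and that of neutrophil markers for D2C7-IT -0.37. The B cell difference of aCD40 was 1.26 without aCD40 day 3 replicate 1. In edgeR 0 genes passed for any agent, where 272, 3914 and 1793 genes had an unadjusted p under 0.05 and DESeq2 called 7, 94 and 8 for aCD40, D2C7-IT and the combination. Without vehicle day 3 replicate 1, 3703 genes passed for D2C7-IT. Without vehicle day 0 replicate 1 it was 4 for aCD40 and 3 for the combination, and 1 for each without replicate 3 of aCD40 or replicate 1 of the combination at day 3. Across the 22280 genes, which are not independent replicates, the day 0 and day 3 fold changes correlated with Pearson's r of 0.17 for aCD40, 0.09 for D2C7-IT and 0.36 for the combination (Spearman's rho 0.04, -0.18 and 0.20). Among genes of at least 5 CPM, r was -0.22 for D2C7-IT and rho -0.03 for aCD40. These fold changes rest on different vehicle tumours on each day.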

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

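All tests of explanations in this part were chosen only after the results were seen, as were the covariate of Egfr and the omission of the 3 libraries of highest Egfr, while the tests of differences between treatments and days were planned.

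Over the 5 tests of a difference between treatments or days, 90 list results passed with the preset correlation and 6 passed with the estimated one as well. Neutrophil markers (-2.81), alternative macrophage genes (-1.11) and endothelial markers (-0.48) lay below the sum of the single agents at day 0. The effect of aCD40 differed between day 3 and day 0 by 4.35 on erythroid genes and by -0.45 on endothelial markers. The effect of the combination differed by 4.12 on erythroid genes. With the preset correlation, these 6 calls held without each of the 12 libraries in turn, and the estimated one was not run without them.

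The rise of neutrophil markers and chemokines after D2C7-IT at day 0 (2.22 and 1.53) was set against 3 technical explanations. Blood left in the tissue would raise red cell genes too, and the erythroid list stood at -0.50. With Egfr adjusted for, as a measure of the share of tumour, the medians were 1.99 and 1.35. This cannot decide the share of tumour, since Egfr is the target of D2C7-IT and overlapped between the groups (36.7 ± 9.66 against 28.5 ± 19.4 CPM). Egfr also varied mostly through the 3 day 3 libraries where it was highest. The rise did not depend on the low depth of vehicle replicate 3, since the medians without that library were 1.86 and 1.21. A response to the immunotoxin or to cell death was not tested, nor was the lack of the control antibody that vehicle received.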

How the results depend on the processing

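Tests with Egfr as a covariate and without the 3 libraries of highest Egfr were chosen only after the results were seen, and the other settings were planned. Where a value below left its side of the threshold, the cause was not tested, except that fewer libraries or an added covariate were used by construction. DESeq2 size factors in edgeR changed 0 of 136 list results and 0 of 270 results of named genes. DESeq2's Wald test called 107 of these 270 that edgeR did not call. The replicate block ended 1 list call. The numbers gave no sign of pairing the tumours: deviations of same-numbered libraries correlated from -0.91 to 0.51, median -0.02 over 84 pairs, and 5 of 24 libraries lay closest to their own number. The 3 libraries of highest Egfr weigh on these deviations, so a weaker pairing is not excluded. At this spread and 3 tumours a group, simulated changes of 2, 4, 8 and 16 times were called for 4%, 58%, 92% and 100% of genes in the comparison of D2C7-IT with vehicle at day 0. Counts of 0 therefore exclude little for changes of 2 or 4 times, and the other comparisons were not simulated.

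DESeq2's Wald test called 17, 133 and 26 genes against vehicle at day 0 for aCD40, D2C7-IT and the combination, and 35, 2790 and 1642 at day 3. It called 6 and 20 for the combination against aCD40 and D2C7-IT at day 0, 205 and 3 at day 3, 5 for non-additivity at day 0, 7, 94 and 8 for the day differences and 2425 for vehicle between days. With only the groups compared, edgeR called 87 genes for D2C7-IT at day 0, 0 for the combination at day 3 and 19 for the combination against D2C7-IT at day 3, and eosinophil and mast cell markers stood at 0.39 in D2C7-IT at day 3 and at 0.01 in vehicle between days. The replicate block gave 9 genes for D2C7-IT at day 0, and 3 and 1 for the day differences of aCD40 and the combination. Without the filter on counts, 3 genes passed for the combination against aCD40 at day 3 and 1 for the day difference of aCD40. Lists called with an estimated correlation were 3, 3 and 3 at day 0 and 2, 0 and 0 at day 3 in the comparisons with vehicle, and fry called 1, 4 and 1, then 2, 1 and 2. Among genes of at least 5 CPM the fold changes of the days correlated with r of 0.11, -0.22 and 0.25 (rho -0.03, -0.38 and 0.13) for aCD40, D2C7-IT and the combination.

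With neuron markers as a covariate, 10, 62 and 2 genes passed against vehicle at day 0, 14 for aCD40 and 2 for the combination at day 3, and 1 and 2 for the combination against aCD40 and D2C7-IT at day 3. Lists called were 11 for D2C7-IT and 21 for the combination at day 3. Calls that turned, here and below by the test's direction, were MHC class II (0.02), monocyte (0.26), pattern recognition (0.48), astrocyte (-0.14), cell cycle (-0.10) and mitochondrial (-0.10) in D2C7-IT at day 3, NK cell (0.29) and mitochondrial (-0.01) in the combination, and cell cycle in the combination against aCD40 (0.53) and in its day difference (0.50). The median alone crossed 0 for the stress list in D2C7-IT at day 0 (-0.03) and cell cycle in vehicle between days (-0.18).

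With Egfr as a covariate, 17, 153 and 44 genes passed against vehicle at day 0, 68 for aCD40 and 47 for the combination at day 3, and 8 and 81 for the combination against aCD40 and D2C7-IT at day 3. Lists called were 24 for aCD40 and 26 for the combination at day 3. Calls that turned were type I interferon (0.07) and cell cycle (0.14) in aCD40 at day 3, MHC class II (0.06), monocyte (0.39), pattern recognition (0.54), cell cycle (0.07) and mitochondrial (-0.10) in D2C7-IT, NK cell (1.18), neuron (-0.07), cell cycle (0.51), mitochondrial (-0.18) and ribosomal (0.03) in the combination, and cell cycle in the combination against aCD40 (0.27) and in its day difference (0.17). The median alone crossed 0 for the stress list in D2C7-IT at day 0 (-0.05) and the astrocyte list in the combination at day 3 (-0.11).

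Without the 3 libraries of highest Egfr, 9, 43 and 2 genes passed against vehicle at day 0, 0 for the combination at day 3 and 2 for the combination against D2C7-IT at day 3. Lists called were 22 for aCD40 and 31 for the combination at day 3. Calls that turned were cell cycle in aCD40 at day 3 (0.61). In D2C7-IT they were interferon-gamma (0.50), MHC class I (0.68), MHC class II (1.08), T cell (0.88), cytotoxic (1.24), NK cell (0.86), monocyte (0.78), pattern recognition (1.07), eosinophil and mast cell (0.64), neuron (-0.02), astrocyte (-0.16), cell cycle (0.98), mitochondrial (-0.23) and ribosomal (0.14). In the combination they were NK cell (2.53), neuron (-0.20), astrocyte (0.03), cell cycle (1.20), mitochondrial (-0.21) and ribosomal (0.28), and cell cycle against aCD40 (0.46). In the day differences they were cell cycle for D2C7-IT (0.71) and type I interferon (0.27) and cell cycle (1.76) for the combination. In vehicle between days they were interferon-gamma (-0.53), NK cell (-0.79), neuron (-0.04), cell cycle (-1.29) and ribosomal (-0.13). The median alone crossed 0, with the call lost, for type I interferon (0.08) and alternative macrophage (0.40) lists in D2C7-IT at day 3 and for eosinophil and mast cell markers (-0.07) in vehicle between days.

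Leaving out each library in turn gave 0 to 4 genes for aCD40 and 0 to 2 for D2C7-IT at day 0. At day 3 it gave 0 to 1364 for aCD40 (1364 without its replicate 1), 0 to 8203 for D2C7-IT and 0 to 6925 for the combination (both highest without vehicle replicate 1), and 0 to 88 for the combination against aCD40. Non-additivity gave 0 to 4 genes at day 0 and 0 to 1 at day 3, the day differences 0 to 4, 0 to 3703 and 0 to 3, and vehicle between days 0 to 9451. Lists called ranged from 7 to 21 for aCD40 and 14 to 26 for D2C7-IT at day 0 and from 8 to 23 for the combination at day 3. In aCD40 at day 0 the monocyte list ranged from -0.25 to 1.22 and the phagosome list from -0.12 to 0.54, lowest without aCD40 replicate 3. In aCD40 at day 3, CD40 and NF-kB ranged from -0.71 to 0.57, interferon-gamma from -1.51 to 0.77, cytotoxic from -0.57 to 0.81 and complement from -0.29 to 0.77, lowest without aCD40 replicate 1, and T cell from -0.13 to 0.90, lowest without vehicle replicate 1. The cell cycle list in the combination against aCD40 at day 3 ranged from -3.05 to 0.45, highest without aCD40 replicate 1.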

Other observations

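The tests of explanations in this part were chosen only after the results were seen, as were the covariate of Egfr and the omission of the 3 libraries of highest Egfr, while the counts of other splits and leaving out single libraries were planned.

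Against aCD40 at day 0, the combination was higher in type I interferon genes (0.50, 23 of 24 members higher) and chemokines (0.23) and lower in T cell markers (-0.53, 2 of 22 higher), each with adjusted p = 0.9 with an estimated correlation. Mx2 stood at 14.3 ± 9.98 CPM against 5 ± 1.98 and the coreceptor gene Cd4 at 2.61 ± 0.915 against 9.97 ± 11.9. The interferon call ended without aCD40 replicate 1 or combination replicate 3, the T cell call without aCD40 replicate 3 or combination replicate 1 or 3, and the chemokine call without combination replicate 2, the medians ranging from 0.26 to 1.26, -0.96 to 0.12 and -0.20 to 1.61 over the alternatives. Choroid plexus and ependymal markers, genes of the ventricle lining, differed widely between tumours of a group, from 0.86 to 4.82 log2 CPM in aCD40 at day 0 and from 1.18 to 4.23 in D2C7-IT at day 3. They stood at 0.47, 0.19 and -0.98 in the 3 libraries of highest Egfr.

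The 3 libraries of highest Egfr (vehicle day 3 replicates 2 and 3 and aCD40 day 3 replicate 1) may have held a larger share of tumour and a smaller share of brain. All 9 values of the neuron, astrocyte and oligodendrocyte lists in these libraries lay more than 1 SD below the mean of the other 21. Sequencing depth was not the cause, since 0 of the 3 totals, 42.0, 37.4 and 34.5 M, lay outside the range of the other 21. Swapped labels of vehicle replicate 1 and aCD40 replicate 1 cannot be told apart from true labels: on 2 of 2 lists, erythroid and B cell, both libraries lay nearer to the others of their own label, but these lists were picked because they differ between the labels. Dissection and tumour growth were not tested.

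The rise of B cell markers in aCD40 tumours at day 3 (2.84) was set against 3 explanations. Blood left in the tissue would raise red cell and B cell genes together, yet the combination, where erythroid genes were as high, differed from aCD40 by -3.60 on the B cell list (adjusted p = 0.19 with an estimated correlation). With Egfr as a covariate the rise was 3.42, and without aCD40 replicate 1, the library of highest B cell level, it was 1.93. A gain of B cells after aCD40 is a hypothesis these values leave open, with levels of 5.32, 3.96 and 1.64 log2 CPM in the 3 tumours.

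The 6 tumours of a comparison can be split in 10 ways, the real one included, too few for a share under 0.05. For D2C7-IT at day 0 and the combination at day 3, 1 split, the real one, called as many genes (18 and 9), and the highest other count was 0. Elsewhere the real count was 0, so all 10 splits were as large whatever they called, and the highest other count was 13782 for aCD40 at day 3, 2822 for vehicle between days, 3 for the combination against D2C7-IT at day 3 and 0 for the rest. The split with 13782 genes sets the 3 libraries of highest Egfr against the other 3, and that with 2822 sets vehicle day 3 replicates 2 and 3 with vehicle day 0 replicate 1, so these counts follow a structure of the samples. Of list calls against vehicle, 5, 4 and 4 of 10 splits gave as many as the real 18, 16 and 15 at day 0, and 10, 5 and 10 as many as the real 13, 19 and 10 at day 3, the highest other counts being 24, 25, 23, 26, 26 and 28. For non-additivity and the day differences, the real count was 0, so all 100 groupings drawn reached it by construction and say nothing of chance, and the highest others were 68 and 9076 for days 0 and 3, and 11728, 67 and 354 for aCD40, D2C7-IT and the combination.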
